A study of Candida albicans and Streptococcus gordonii and Streptococcus gordonii
Candida albicans with 15 samples.

How the data were processed

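RNA sequencing counts of C. albicans and S. gordonii were taken from the deposited tables, which per the file headers hold raw counts of sequence tags on 6653 C. albicans features and 2051 S. gordonii genes, with no normalization. Per the labels, hyphae were induced for 2 h in a glucose medium, RNA was depleted of ribosomal RNA, and the libraries were made with ScriptSeq v2. According to the submitters' processing notes, CASAVA 1.8.2, Bowtie 1.0.0, TopHat2 2.0.8, bedtools (no version given) and DESeq 1.12.1 were used, with no statement of the role of each. The genome build, the strand setting and the treatment of reads that match several places are not stated, so that values of near-identical genes are uncertain. No coordinates are given, because the gene identifiers of the tables are not in the annotation at hand. The labels call one medium S. gordonii medium while the column header names the growth medium, and the text uses the label. The header gives it as growth medium (YPT-Glc) and uses the word spent only for the C. albicans medium. Whether this medium had been spent by bacteria or was fresh is not stated outright. Spike-in RNA, added per the labels, was not analysed here.

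The C. albicans features comprised 6196 protein-coding genes, 20 mitochondrially encoded protein genes, 9 ribosomal RNA, 156 transfer RNA and 81 other noncoding features, and 191 repeats and regions. Only the protein-coding and mitochondrially encoded protein genes entered library sizes and tests, and all other features were left out. TAR1, which overlaps ribosomal DNA, was put with ribosomal RNA after the data were seen. Depth varied from 3301440 to 13322430 counts for C. albicans and from 5349117 to 29180795 for S. gordonii. Shares of single libraries carry Wilson 95% intervals, which cover counting error only. No group was left out, and every column of both tables was assigned to a library by its header.

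Groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, except where the text says otherwise. Counts were tested in edgeR 4.0.16 (R 4.3.3) with trimmed-mean factors, the filterByExpr filter and the quasi-likelihood F-test, with the 9 libraries of an organism in 1 fit and 6 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. The SE beside an edgeR log2 fold change is its absolute value divided by the square root of the F statistic. It was thus derived from the test and not estimated apart from it. Levels are given as counts scaled to library size (CPM), as mean ± SD with n = 3. Of the 6 comparisons, 3 concern each organism, and comparisons of 1 organism share a group, so that they are not independent.

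Whether replicate numbers pair the libraries was checked by correlating, across genes, the deviations of libraries from their group mean. A correlation of at least 0.1 for each number was required. It lay between 0.347 and 0.599 for co-culture against C. albicans alone, between 0.224 and 0.728 for medium against alone, between 0.253 and 0.689 for co-culture against medium, and between 0.481 and 0.620 for S. gordonii in co-culture against medium. Libraries of unlike numbers reached 0.109, 0.623, 0.613 and -0.0729 in the same order. Of 6 libraries, 6, 4, 4 and 6 correlated best with their own number. Deviations from a group mean cancel out, so that a replicate 1 standing apart would by itself raise the correlations of numbers 2 and 3. For medium against alone and co-culture against medium of C. albicans, the check therefore cannot show that numbers 2 and 3 pair. Since each number passed, values for these comparisons are also given with the replicate number as a block, where that changes a call or moves a count by over 1.5 times. The block leaves 4 residual degrees of freedom. For S. gordonii against bacteria alone the lowest values were 0.0201 and 0.0474, and those comparisons were not taken as paired.

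Gene lists were matched by symbol or product name: 23 lists for C. albicans and 24 for S. gordonii. A further list, of S. gordonii ribosomal and transfer RNA, had no members in the table. The pattern for the F-type ATP synthase also took V-type subunits. Lists were tested against all other genes with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, adjusted over the lists of 1 organism and comparison. Camera with an estimated correlation, and fry in one direction and in mixed directions, were alternatives. Fry asks whether the genes of a list change at all, on balance one way or in either direction, and does not set them against other genes. For no list past camera did median, mean and test differ in sign, or the sign of the median change with library totals or median-ratio factors. The sign of the median changed with either for 18 of the other lists, counted over all comparisons. Among other lists, the signs of median, mean and test differed for 1, 4 and 4 lists of C. albicans (co-culture against alone, medium against alone, co-culture against medium) and for 8, 4 and 5 of S. gordonii.

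Named genes were, per comparison, the 8 largest rises and falls (5 where co-culture was compared with medium or medium with alone) among genes past the threshold with at least 10 CPM and no overlap between groups, up to 4 members past the threshold of each list, and the 2 members with the lowest p of lists past camera. The rule asked for a symbol or product name, and for C. albicans an opening of the description such as Putative or Protein similar to was read as one, after the data were seen. Genes outside the rule are marked as chosen after their values were seen.

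Alternatives were DESeq2 1.42.0, median-ratio factors, library totals alone, no filter on low counts, at least 10 counts in every library of a group, the 2 compared groups alone, the replicate block, an absolute log2 fold change of at least 1, thinning to the smallest total, noncoding features kept, and each library left out in turn. Added after the data were seen were the fits without the replicate 1 libraries, with and without the block, and DESeq2 with the block. On simulated counts with a replicate effect like that of the C. albicans libraries, the fit by groups recovered 0.667% of genes changed 2-fold and 54.7% of those changed 4-fold, and the fit with the block 56.7% and 96.0%. The S. gordonii figures were 29.0% and 85.7%, and 74.7% and 95.3% with the block. The simulated effect came from the fit with the block and was shared by all groups, so that this gain was built in. The S. gordonii simulation concerned co-culture against alone, which was not taken as paired. Without a replicate effect the fit by groups recovered 7% and 67.3% in C. albicans, and the block 4.67% and 52.3%. For S. gordonii these were 40.3% and 90.0%, and 38.7% and 89.3%. False calls made up at most 4.85% of the calls. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.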

Results

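RNA depleted of ribosomal RNA was sequenced from a fungus and a bacterium kept apart or together. These were the yeast-to-hypha switching fungus Candida albicans (strain SC5314, the standard laboratory reference) and the oral bacterium Streptococcus gordonii (strain Challis). The labels give S. gordonii substrain CH1, except that co-culture replicates 1, 2 and 3 are labelled CH1, CH2 and CH3, and whether these are substrains or replicate numbers is not stated. The 15 libraries fall into 5 groups of 3, which the labels call biological triplicates: C. albicans hyphae formed for 2 h, read here as harvested at that point, hyphae kept for 1 h more with S. gordonii cells, hyphae kept for 1 h more in S. gordonii medium, S. gordonii kept for 1 h alone, and S. gordonii kept for 1 h in C. albicans medium. The co-culture libraries were counted on both genomes, so that each organism had 9 libraries and 3 comparisons. Total counts of replicates 1, 2 and 3 on the C. albicans features were 13322430, 10456972 and 10260817 alone, 12717630, 13257367 and 10509475 in medium, and 5050207, 3301440 and 5364722 in co-culture. On the S. gordonii genes they were 20176595, 11682016 and 10557390 alone, 29180795, 9682974 and 13131863 in medium, and 10357772, 5349117 and 7381944 in co-culture. C. albicans supplied 37.7 ± 4.67% (SD, n = 3) of the counts of the co-culture libraries. Its part includes ribosomal RNA and other noncoding features, while that of S. gordonii holds protein-coding genes only, so that this is not a share of protein gene counts. Ribosomal RNA took 12.6 ± 0.512% of the C. albicans counts alone, 11.7 ± 2.31% in medium and 13.5 ± 3.06% in co-culture.

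The C. albicans libraries of replicate 1 stood apart from the other replicates in all 3 groups. A first component holding 50.5% of the variance of the C. albicans libraries gave the 3 replicate 1 libraries scores from 36.3 to 38.8 and the other 6 scores from -29.2 to -7.20. Co-culture was separated by the second component, which held 20.5%. Mitochondrially encoded genes took 6.71%, 3.84% and 5.98% of the C. albicans counts in replicate 1 of the alone, medium and co-culture groups, and from 1.90 to 3.39% in the other 6 libraries. The first component of the S. gordonii libraries held 35.5% of the variance and placed co-culture replicates 2 and 3 at -19.2 and -19.9, but co-culture replicate 1 at 12.2, between replicate 1 of the medium (9.75) and alone groups (18.3). Replicate 2 of the alone group of S. gordonii lay by itself on the second component, with a score of -28.3 against scores from -1.20 to 6.44. Libraries that should hold 1 organism alone held small shares of counts on the genome of the other, between 0.0210 and 0.324%, as shown in the plot of other-organism counts.

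The first comparison asked how C. albicans hyphae that had met S. gordonii differed from hyphae alone, which were harvested before the bacteria were added if the labels are read rightly. In co-culture 4 of 10 arginine synthesis genes rose, and the arginine breakdown genes CAR1 and CAR2 fell. ARG1 (orf19.7469), the argininosuccinate synthase, stood at 1608 ± 983 CPM (counts scaled to library size; SD, n = 3) in co-culture and at 63.0 ± 47.7 alone, a log2 fold change of 4.67 (SE 0.73, adjusted p = 0.0302 by edgeR's quasi-likelihood test). ARG3 (orf19.5610), the ornithine carbamoyltransferase, rose by 3.26 on the log2 scale (SE 0.49, adjusted p = 0.0268), ECM42 (orf19.6500), an ornithine acetyltransferase, by 2.92 (SE 0.39, adjusted p = 0.0197), and ARG5,6 (orf19.4788), which carries an early pair of steps of the same pathway, by 2.90 (SE 0.43, adjusted p = 0.0255). CAR1 (orf19.3934), the arginase that opens arginine breakdown, went from 116 ± 38.7 to 13.3 ± 2.95 CPM (log2 fold change -3.13, SE 0.34, adjusted p = 0.00935), and the ornithine aminotransferase CAR2 (orf19.5641) changed by -2.50 (SE 0.40, adjusted p = 0.0358).

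The putative sulfiredoxin orf19.3537, an enzyme class that restores oxidised peroxiredoxins and in none of the lists, rose from 5.90 ± 2.00 to 225 ± 1.25 CPM (log2 fold change 5.24, SE 0.29, adjusted p = 5.94e-05 by edgeR). Of 36 oxidative stress genes 3 rose: TRR1 (orf19.4290), the thioredoxin reductase, from 458 ± 140 to 2357 ± 135 CPM (2.36, SE 0.28, adjusted p = 0.0146), GPX2, similar to glutathione peroxidase, by 1.77 (SE 0.30, adjusted p = 0.0409), and OYE32, an oxidoreductase, by 2.58 (SE 0.34, adjusted p = 0.0197). BIO2 (orf19.2593), the putative biotin synthase, rose by 3.68 (SE 0.45, adjusted p = 0.0146). The hyphal adhesin ALS3 (orf19.1816) went from 1853 ± 495 to 7816 ± 1107 CPM (2.08, SE 0.28, adjusted p = 0.0197), beside rises of the filamentation regulators TEC1 (2.42, SE 0.39, adjusted p = 0.0358) and CPH1 (1.33, SE 0.22, adjusted p = 0.0409). Of the iron list, the ferric reductase-like gene CFL11 rose by 2.74 (SE 0.38, adjusted p = 0.0218), while the multicopper oxidase FET3 changed by -2.89 (SE 0.43, adjusted p = 0.0255) and the siderophore transporter SIT1 by -1.81 (SE 0.27, adjusted p = 0.0255). CFL1, also similar to ferric reductases but outside that list, changed by -1.94 (SE 0.26, adjusted p = 0.0197). SOU1, an enzyme of sorbose use, changed by -2.22 (SE 0.37, adjusted p = 0.0409).

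**Figure D1:**
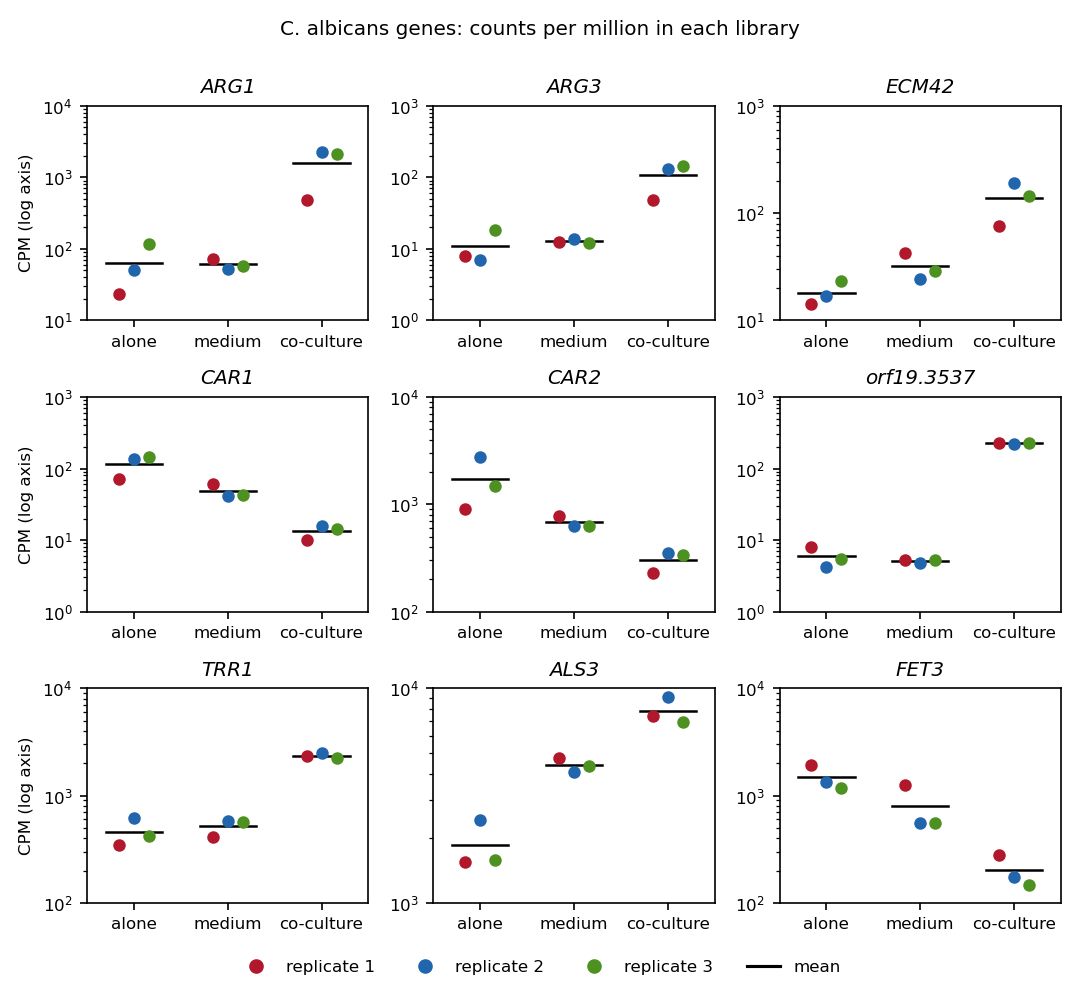
Counts scaled to library size (CPM, log axis) of 9 C. albicans genes in the libraries alone, in S. gordonii medium and in co-culture; points are libraries coloured by replicate number and bars are group means. The sulfiredoxin orf19.3537 lay at 225 ± 1.25 CPM in co-culture and 5.07 ± 0.308 in medium, and ARG1 at 1608 ± 983 and 60.9 ± 9.86.

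Of 5985 C. albicans genes tested, 26 changed between co-culture and alone, 19 higher and 7 lower, all at least 2-fold. With the replicate number as a block, 154 changed (99 higher, 55 lower), the 26 among them. The 2 groups did not overlap for 11.1% of the genes. Chance gives 10% for 6 libraries without a replicate effect. An effect shared by the groups lowers that share, so that 10% is not the chance level of these libraries. The count was 17, 9 and 2 without replicate 1, 2 or 3 of the alone group and 58, 4 and 2 without replicate 1, 2 or 3 of the co-culture. The genes orf19.3537 and orf19.2165, an open reading frame annotated as induced by nitric oxide (3.18, SE 0.22, adjusted p = 0.000238 by edgeR), passed whichever of the 6 libraries was left out; the latter and the remaining changed genes, BUL1, ARO9, ARR3, orf19.3107, orf19.2506 and orf19.3694, fall outside the naming rule and were chosen after their values were seen. Of the 24 others, CAR1 passed in 4 of these 6 fits, 7 genes in 3, 2 in 2, 12 in only 1 (the 4 arginine synthesis genes, CAR2, TEC1, CPH1, GPX2 and FET3 among them) and 2 in none. DESeq2 called 137, edgeR fitted to the compared groups alone called 2, and edgeR without the replicate 1 libraries, a choice made after they were seen to stand apart, called 222.

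By list, 4 of 10 arginine synthesis genes rose and none fell, 8 rose adjusted over the list alone, and 8 rose with the replicate block. Their median log2 fold change was 2.99 (camera adjusted p = 5.04e-16, and adjusted p = 0.142 with an estimated correlation). CPA1, of the same pathway, had a log2 fold change of 3.69 (SE 0.66, adjusted p = 0.0575) and passed with the block (adjusted p = 0.000457). Of 20 hypha-associated genes 3 rose, 11 adjusted over the list alone and 8 with the block, with a median of 1.00 (camera adjusted p = 5.64e-14). This was the 1 list that also passed with an estimated correlation (adjusted p = 0.00908), though not when the block was added (adjusted p = 0.124 with an estimated correlation). ECE1, which encodes candidalysin, and IHD1, a hyphal wall gene, had log2 fold changes of 1.83 (SE 0.41, adjusted p = 0.150) and 1.76 (SE 0.37, adjusted p = 0.109) and rose with the block (adjusted p = 0.0324 and 0.00103). Of 36 oxidative stress genes 3 rose, adjusted over the list alone 14 rose and 2 fell, and 14 rose with the block (median 0.61, camera adjusted p = 1.32e-08, adjusted p = 0.278 with an estimated correlation). The catalase CAT1 and the peroxiredoxins TSA1 and TSA1B, chosen after their values were seen, were among those that rose with the block, by 1.88 (SE 0.31, adjusted p = 0.00649), 1.62 (SE 0.23, adjusted p = 0.00307) and 1.62 (SE 0.23, adjusted p = 0.00310); the last pair are near-identical copies, and how shared reads were counted is not stated. In the family of ALS adhesins and EAP1, 1 of 10 rose, 3 adjusted over the list alone and 4 with the block (ALS3, ALS1, ALS5 and EAP1; median 0.60, camera adjusted p = 0.000386, adjusted p = 0.373 with an estimated correlation), and reads shared among these similar genes leave single members uncertain. ALS3 and ALS1 are also in the hypha-associated list, and ALS4 in that of yeast-form and repressor genes, so that these lists are not separate results in any comparison.

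Amino acid synthesis outside arginine and sulfur also stood higher, with 0 of 53 genes past the threshold in edgeR (8 higher and 1 lower adjusted over the list alone, and PRO3 lower with the block), a median of 0.79 and a camera adjusted p of 4.98e-10 (adjusted p = 0.449 with an estimated correlation). Its lysine genes LYS22 and LYS2 had log2 fold changes of 3.59 (SE 0.85, adjusted p = 0.161) and 1.71 (SE 0.45, adjusted p = 0.233). A further 5 lists stood lower than other genes by camera without a member past the threshold. These were 33 cell cycle and histone genes (median -0.52, adjusted p = 5.46e-05, 0.373 as adjusted p with an estimated correlation), among them the mitotic cyclin CLB4 at -0.90 (SE 0.25, adjusted p = 0.291). They also held 62 ribosome biogenesis genes (median -0.49, adjusted p = 3.95e-05, adjusted p = 0.710 with an estimated correlation) and 71 cytosolic ribosomal protein genes (median -0.26, adjusted p = 0.000911, adjusted p = 0.710 with an estimated correlation), with UTP8 at -0.81 (SE 0.30, adjusted p = 0.480) and RPP2B at -0.56 (SE 0.22, adjusted p = 0.558). The 10 yeast-form and hyphal repressor genes had a median of -0.43 (adjusted p = 0.00223, adjusted p = 0.373 with an estimated correlation), and 1 of them, the mannosyltransferase gene RHD1, fell adjusted over the list alone and with the block (-1.67, SE 0.20, adjusted p = 0.00105). The 23 genes of the glyoxylate cycle, gluconeogenesis and fatty acid oxidation had a median of -0.54 (adjusted p = 0.00819, adjusted p = 0.710 with an estimated correlation), with the thiolase gene FOX3 at -1.68 (SE 0.58, adjusted p = 0.444).

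The other 13 lists had camera adjusted p between 0.0580 and 0.971. They covered drug efflux and ergosterol, glycolysis, heat shock, hexose transporters, iron, nitrogen and amino acid uptake, oxidative phosphorylation, secreted aspartyl proteases, sulfur, mitochondrially encoded genes, the tricarboxylic acid cycle, white-opaque and mating genes, and zinc and phosphate. Among 30 iron genes 1 rose and 2 fell (1 and 3 adjusted over the list alone). No member of the other 12 passed over all genes in edgeR, and adjusted over the list alone 2 nitrogen uptake genes rose and 2 fell, 1 hexose transporter fell and 2 white-opaque and mating genes rose. With the block, drug efflux genes stood higher (adjusted p = 0.0382) and hexose transporters and mitochondrially encoded genes lower (adjusted p = 0.0432 and 0.0352), with adjusted p = 0.820, 0.820 and 0.826 with an estimated correlation. Of the mitochondrial genes, NAD2 and NAD3 went from -0.54 and -0.65 to 0.05 and 0.004 without C. albicans alone replicate 1, in the fit without the block. In the 13 lists 16 members passed with the block, 7 higher and 9 lower, 3 of which (CFL11, FET3 and SIT1) also passed without it. Among them were HSP12, a stress protein gene, at -3.48 (SE 0.37, adjusted p = 0.000554), the white-phase gene WH11 at -4.34 (SE 0.46, adjusted p = 0.000554), the glucose transporter gene HGT6 at 1.47 (SE 0.26, adjusted p = 0.00945) and the peptide transporter gene OPT4 at 2.11 (SE 0.46, adjusted p = 0.0341). HSP12 has a near-identical copy, orf19.4216, at -3.56 (SE 0.35, adjusted p = 0.000335), and how reads shared by both were counted is not stated. Over the alternatives HSP12 lay between -4.92 and -1.85 and WH11 between -5.99 and -2.21, each past the threshold in 4 of 18.

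**Figure D2:**
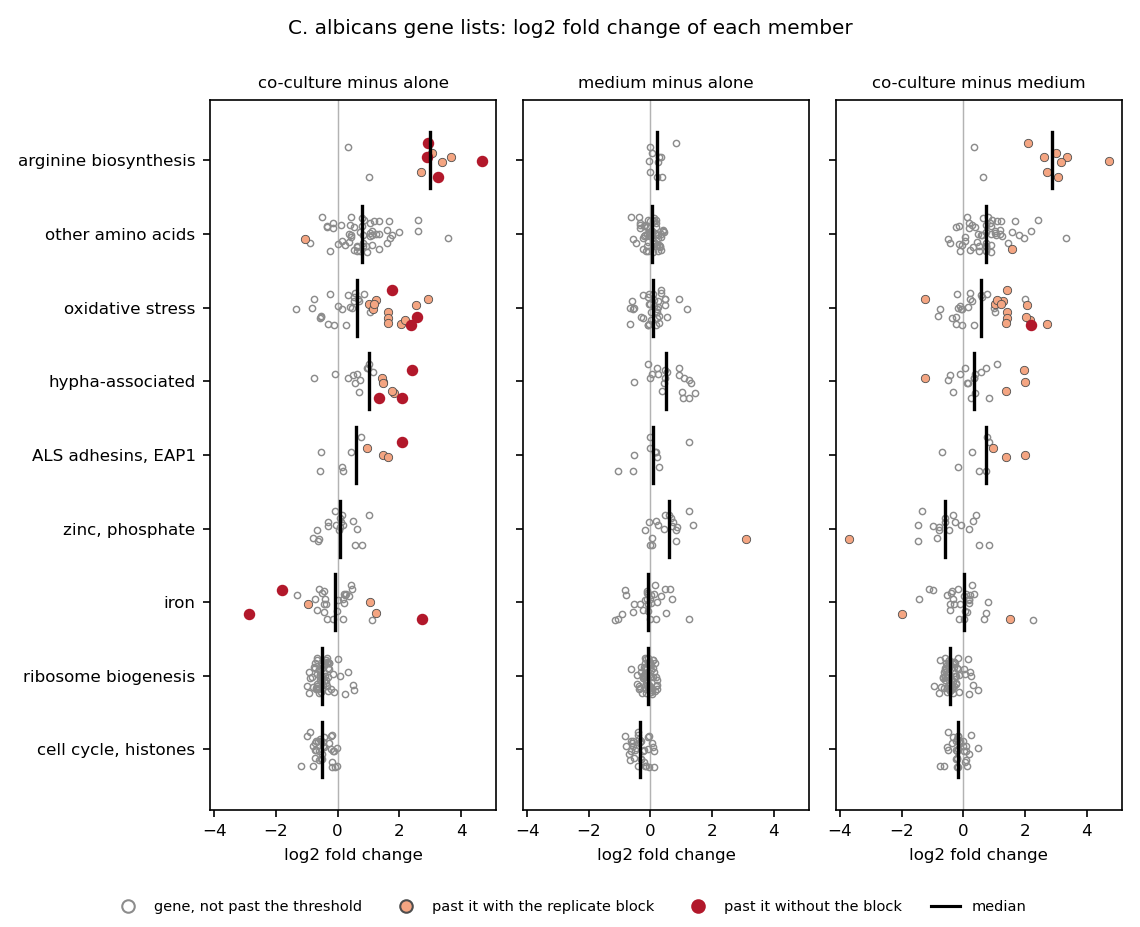
Log2 fold change of each member of 9 C. albicans gene lists (circles) in the 3 comparisons, with the median as a bar; red circles passed an adjusted p of 0.05, orange circles passed it with the replicate block, and open circles did not pass. The arginine median was 2.99 in co-culture against alone, 0.22 in medium against alone and 2.87 in co-culture against medium.

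The second comparison set hyphae kept 1 h in S. gordonii medium against hyphae alone. The labels give 2 h for the latter and no later step; if they were harvested then, the comparison holds both the medium and the time. The column header names that medium as growth medium (YPT-Glc), without the word spent that it gives the C. albicans medium. Whether bacteria had spent it or it was fresh is not stated outright. The phosphate transporter gene PHO89 (orf19.4599) stood at 300.5 ± 156 CPM in medium and 35.0 ± 8.26 alone, and rose in the fit with the replicate block (log2 fold change 3.04, SE 0.32, adjusted p = 0.00655); without it the change was 3.10 (SE 0.55, adjusted p = 0.9998 by edgeR). The aquaporin gene AQY1 fell with the block (-2.003, SE 0.25, adjusted p = 0.0158) and was chosen after its values were seen. ALS3, CPH1 and HWP1, the gene of a hyphal wall protein that binds host cells, had log2 fold changes of 1.24 (SE 0.27), 1.07 (SE 0.22) and 1.31 (SE 0.42), none past the threshold, and HWP1 stood at 0.69 without medium replicate 1. Across 5985 genes, 0 passed in edgeR, 78 had an unadjusted p under 0.05, 2 passed with the replicate block and 4 passed in DESeq2. The groups did not overlap for 4.33% of genes, where chance gives 10% only without a replicate effect.

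Hypha-associated genes were the list with the lowest p in this comparison. None of the 20 passed over all genes and 8 rose adjusted over the list alone, with a median of 0.50 (camera adjusted p = 2.43e-17, adjusted p = 0.00468 with an estimated correlation, 0.0822 when the block was added). Zinc and phosphate genes stood higher (19 genes, 2 higher adjusted over the list alone, median 0.62, adjusted p = 9.07e-11, adjusted p = 0.101 with an estimated correlation), with VTC3, a polyphosphate synthetase gene, at 0.85 (SE 0.23, adjusted p = 0.9998). Sulfur and methionine genes (median 0.38, adjusted p = 0.00491) and arginine synthesis genes (median 0.22, adjusted p = 0.0305) stood higher too, without a member past the threshold and with adjusted p = 0.439 and 0.728 with an estimated correlation. Of the arginine genes, ARG5,6 went from 0.29 to -0.25 without the replicate 1 libraries and CPA1 from 0.34 to -0.01 without C. albicans alone replicate 1. Lower by camera were yeast-form and repressor genes (median -0.32, adjusted p = 0.000422), hexose transporters (-0.33, 0.000526, 1 lower adjusted over the list alone), cell cycle genes (-0.34, 0.000544), mitochondrially encoded genes (-0.55, 0.00222), glyoxylate cycle and related genes (-0.37, 0.00223), nitrogen uptake genes (-0.23, 0.00470) and glycolysis genes (-0.35, 0.0209). For these 7 the adjusted p with an estimated correlation lay between 0.312 and 0.728, and the glycerol transporter HGT10 had the lowest p of the hexose list at -1.87 (SE 0.41, adjusted p = 0.9998). Mitochondrially encoded genes took 6.71, 2.22 and 3.39% of the C. albicans counts in replicates 1, 2 and 3 alone and 3.84, 2.88 and 2.33% in medium, and without replicate 1 of the alone group the log2 fold changes of NAD2 and NAD3 went from -0.72 and -0.79 to -0.13 and -0.14. The other 12 lists had camera adjusted p between 0.0890 and 0.999; oxidative stress genes had a median of 0.09 and other amino acid synthesis genes of 0.06, and adjusted over the list alone 1 gene of the ALS family rose.

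The third comparison, of co-culture with the medium group, holds the time after induction equal and sets hyphae with bacteria against hyphae without. The sulfiredoxin orf19.3537 rose from 5.07 ± 0.308 to 225 ± 1.25 CPM (log2 fold change 5.47, SE 0.30, adjusted p = 4.45e-05 by edgeR) and TRR1 from 517 ± 94.9 to 2357 ± 135 CPM (2.19, SE 0.28, adjusted p = 0.0373). With orf19.2165 (3.07, SE 0.22, adjusted p = 0.000309), chosen after its values were seen, they made up the 3 genes that changed among 5985. With the replicate block 79 changed, 62 higher and 17 lower. Among them ARG1 rose by 4.37 (SE 0.54, adjusted p = 0.00193), CAT1 by 2.66 (SE 0.315, adjusted p = 0.00193), BIO2 by 2.94 (SE 0.40, adjusted p = 0.00383) and the adhesin gene ALS1 by 2.00 (SE 0.24, adjusted p = 0.00193), and PHO89 fell by 3.77 (SE 0.34, adjusted p = 0.000444), FET3 by 1.93 (SE 0.20, adjusted p = 0.000832) and CAR1 by 1.90 (SE 0.31, adjusted p = 0.0118). Without the block the same genes had adjusted p between 0.0572 and 0.154. Without replicate 1 of the co-culture 37 genes changed; without any other of the 6 libraries 2 did, and orf19.3537 and orf19.2165 passed each time. DESeq2 called 63, edgeR on the compared groups alone 5, and edgeR without the replicate 1 libraries 107. The groups did not overlap for 10.6% of genes, where chance gives 10% only without a replicate effect.

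Arginine synthesis was again the list with the lowest p: 0 of 10 genes passed over all genes in edgeR, 8 rose adjusted over the list alone and 8 with the block, with a median of 2.87 (camera adjusted p = 1.48e-17, adjusted p = 0.227 with an estimated correlation). Of 36 oxidative stress genes 1 rose, 13 adjusted over the list alone, and with the block 13 rose and 1 fell (median 0.59, adjusted p = 5.88e-08, adjusted p = 0.235 with an estimated correlation). Other amino acid synthesis genes had a median of 0.74 (adjusted p = 2.86e-12, adjusted p = 0.393 with an estimated correlation), and LYS4 of the lysine pathway rose with the block (1.46, SE 0.31, adjusted p = 0.0489). The ALS and EAP1 family had a median of 0.74 (3 higher adjusted over the list alone and with the block, adjusted p = 3.40e-05, adjusted p = 0.295 with an estimated correlation). Hypha-associated genes had a median of 0.35 (3 higher adjusted over the list alone, adjusted p = 0.00160, adjusted p = 0.227 with an estimated correlation); with the block 3 rose and the superoxide dismutase gene SOD5 fell (-1.60, SE 0.34, adjusted p = 0.0475). Zinc and phosphate genes stood lower (median -0.60, 4 lower adjusted over the list alone, adjusted p = 1.07e-05, adjusted p = 0.235 with an estimated correlation), as did ribosome biogenesis (-0.42, 1.07e-05), ribosomal protein (-0.16, 0.0162) and cell cycle genes (-0.16, 0.0387), each with adjusted p = 0.865 with an estimated correlation. The other 14 lists had camera adjusted p between 0.318 and 0.919; adjusted over the list alone, 2 nitrogen uptake genes rose, and 1 iron gene rose and 2 fell. In them the alternative oxidase gene AOX2 (2.47, SE 0.44, adjusted p = 0.0171) and the multidrug transporter gene MDR1 (1.34, SE 0.285, adjusted p = 0.0481) rose with the block.

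For S. gordonii, co-culture was first compared with bacteria alone. Purine genes, aromatic amino acid genes and ribosomal protein genes stood higher as groups by camera, though with adjusted p between 0.329 and 0.749 with an estimated correlation, and no gene passed in edgeR. The xanthine permease gene pbuX stood at 916 ± 276 CPM in co-culture and 324 ± 12.9 alone (2.83-fold, adjusted p = 0.0525), and gtfG, whose enzyme makes glucan from sucrose, at 717 ± 242 and 2653 ± 1093 (-1.89, SE 0.33, adjusted p = 0.0650). Across 2046 genes, 0 passed in edgeR, 178 had an unadjusted p under 0.05, and DESeq2 called 56, 51 higher and 5 lower. Without replicate 1 of the co-culture edgeR called 138, and 0 without any other library. The co-culture libraries left in the fit with 138 are those labelled CH2 and CH3. If these are substrains, substrain and co-culture cannot be told apart there. The groups did not overlap for 10.0% of genes, the share that chance gives without a replicate effect.

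Of 14 purine synthesis genes 0 passed over all genes and 9 rose adjusted over the list alone, with a median of 1.27 (camera adjusted p = 3.96e-08, adjusted p = 0.720 with an estimated correlation). In it purK, of the carboxylation step, had a log2 fold change of 2.08 (SE 0.42, adjusted p = 0.0998) and purF, which opens the pathway, of 1.27 (SE 0.29, adjusted p = 0.183). Aromatic amino acid genes had a median of 0.40 over 21 members, 8 higher adjusted over the list alone (adjusted p = 3.73e-10, adjusted p = 0.329 with an estimated correlation), with the tryptophan genes trpF at 1.67 (SE 0.39, adjusted p = 0.183) and trpB-1 at 1.21 (SE 0.31, adjusted p = 0.195). Of 54 ribosomal protein genes 42 had a positive log2 fold change and 0 passed (median 0.49, adjusted p = 4.59e-11, adjusted p = 0.749 with an estimated correlation), for example rplO at 0.96 (SE 0.27, adjusted p = 0.215) and rpsS at 1.04 (SE 0.30, adjusted p = 0.219). The 13 fatty acid synthesis genes had a median of 0.31 (adjusted p = 0.0186, adjusted p = 0.999 with an estimated correlation), with accC at 0.62 (SE 0.30, adjusted p = 0.614). The other 20 lists had camera adjusted p between 0.210 and 0.998. They were surface adhesins and sortase, arginine synthesis, the arginine deiminase pathway, histidine and branched-chain synthesis, amino acid transport, competence, oxidative stress, heat shock, glycolysis, the phosphotransferase system, lactose and galactose use, polysaccharide and maltodextrin use, pyrimidine synthesis, metal transport, ATP synthase, aminoacyl-tRNA synthetases, signalling systems, cell wall synthesis and mobile elements. The arginine deiminase pathway, by which the bacterium makes energy from arginine, had a median of -0.01 over 6 genes (adjusted p = 0.908) and arginine synthesis of -0.19 over 9 (adjusted p = 0.790). Adjusted over the list alone, gtfG fell among surface proteins, malQ and glgP-2 fell among maltodextrin genes, and 1 mobile element gene rose.

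**Figure D3:**
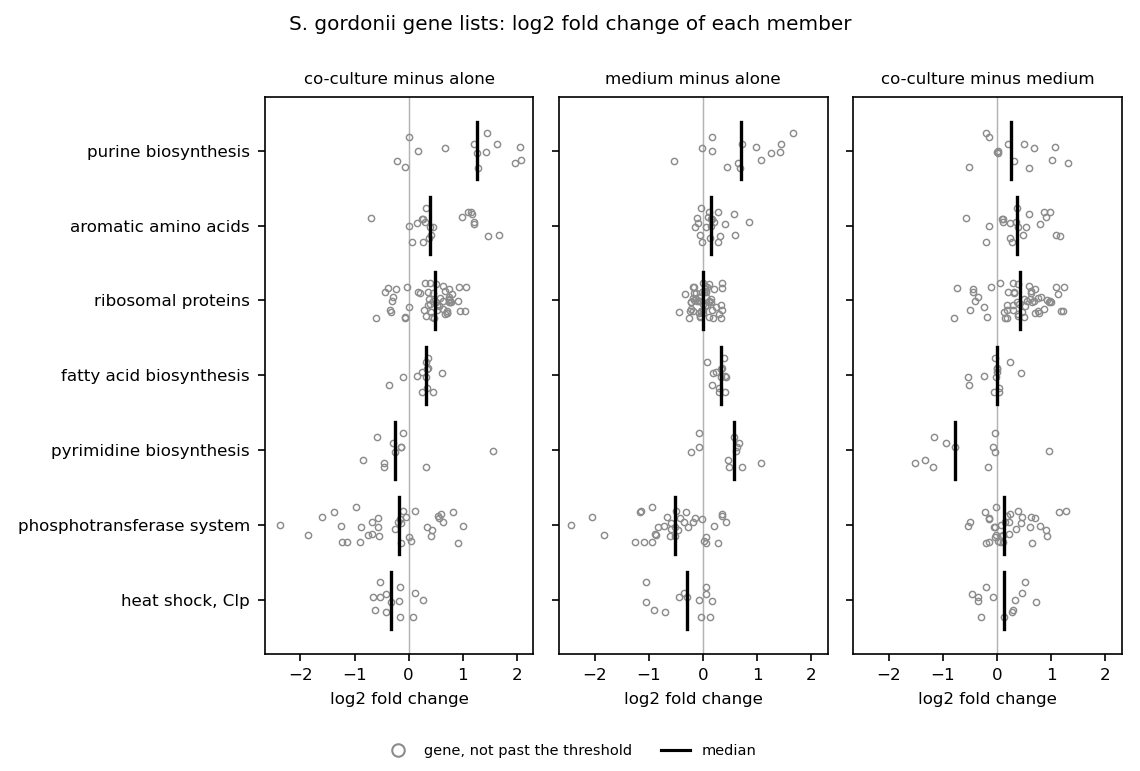
Log2 fold change of each member of 7 S. gordonii gene lists (circles) in the 3 comparisons, with the median as a bar; no gene passed an adjusted p of 0.05 over all genes in edgeR. The purine median was 1.27 in co-culture against alone and 0.70 in medium against alone.

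S. gordonii in C. albicans medium was then compared with bacteria alone. Of 14 purine genes 4 rose adjusted over the list alone (median 0.70, camera adjusted p = 2.36e-11, adjusted p = 0.434 with an estimated correlation). Among them purH stood at 319 ± 172 CPM in medium and 101 ± 19.3 alone (log2 fold change 1.66, SE 0.41) and purF at 1.25 (SE 0.29), both at an adjusted p of 0.9999 over all genes. No gene passed: of 2046 tested, edgeR and DESeq2 each called 0, and 34 had an unadjusted p under 0.05 in edgeR. The groups did not overlap for 6.30% of genes, against 10% by chance without a replicate effect. All 13 fatty acid synthesis genes had positive values (median 0.33, adjusted p = 1.14e-06, adjusted p = 0.572 with an estimated correlation). Aromatic amino acid genes (median 0.14, adjusted p = 7.67e-05), aminoacyl-tRNA synthetases (0.07, 0.0138) and pyrimidine genes (0.58, 0.0138) stood higher, and heat shock and Clp genes (-0.30, 0.0194) and the phosphotransferase system (-0.51, 0.0194) lower, with adjusted p between 0.434 and 0.862 with an estimated correlation. Examples were trpC at 0.85 (SE 0.33) and the chaperone genes grpE at -1.05 (SE 0.39) and groES at -1.05 (SE 0.39), none past the threshold. The pyrimidine gene pyrE went from 1.07 (SE 0.73) to -0.02 without medium replicate 2, and the phosphotransferase genes SGO_1791 and SGO_1789 from -2.44 (SE 1.116) and -1.83 (SE 0.84) to -0.03 and 0.17 without S. gordonii alone replicate 2, the library that lay by itself. Without that library grpE and groES stood at -0.61 and -0.46. The other 17 lists had camera adjusted p between 0.0901 and 0.973.

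Between co-culture and C. albicans medium, S. gordonii ribosomal protein genes stood higher with the fungal cells present. Of 54 members 0 passed over all genes and 10 rose adjusted over the list alone (median 0.42, camera adjusted p = 5.16e-10, adjusted p = 0.978 with an estimated correlation), among them rplO at 2709 ± 825 against 1189 ± 186 CPM (log2 fold change 1.19, SE 0.27, adjusted p = 0.593) and rpsS at 1.22 (SE 0.30, adjusted p = 0.593). Aromatic amino acid genes had a median of 0.36 (adjusted p = 1.34e-05, adjusted p = 0.978 with an estimated correlation), with trpA at 1.15 (SE 0.40, adjusted p = 0.666). The other 22 lists, purine genes with a median of 0.25 among them, had camera adjusted p between 0.0724 and 0.992. Over 2046 genes edgeR called 0, with 147 at an unadjusted p under 0.05, and DESeq2 called 11, all higher, among them the adenylate kinase gene adk and the RNA polymerase gene rpoA, chosen after their values were seen. Without replicate 1 of the co-culture edgeR called 32, and 0 without any other library. The fit with 32 again holds only the co-culture libraries labelled CH2 and CH3, so that a difference of substrain cannot be told apart from co-culture. The groups did not overlap for 10.4% of genes, where chance gives 10% only without a replicate effect.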

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

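The tests in this part, or the limits they use, were chosen after the results they measure were seen. Groups of 3 libraries are too small for a test of single libraries that stand apart.

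Every library of a single organism held counts on genes of the other, above the 3 counts that a count of 0 allows. C. albicans counts in replicates 1, 2 and 3 were 37350, 2276 and 4806 for S. gordonii in C. albicans medium and 5799, 2697 and 2429 for S. gordonii alone. S. gordonii counts were 43247, 2439 and 3027 for C. albicans alone and 11799, 2782 and 3206 for C. albicans in S. gordonii medium. The highest shares were 0.324% (Wilson 95% interval 0.321 to 0.327) in C. albicans alone replicate 1, where 1780 S. gordonii genes had a count, and 0.128% (0.127 to 0.129) in S. gordonii in C. albicans medium replicate 1, where 3522 of 6216 C. albicans genes had one.

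In 12 of 12 libraries the profile of the other organism over protein genes correlated more with libraries of that organism from its own side (replicate 1, or replicates 2 and 3). A profile set by sequence similarity could lean to the same side in every library. If it leaned to replicates 2 and 3, their libraries would give this result too, so that they cannot decide. The lean of the replicate 1 libraries to replicate 1 argues against own reads counted on protein genes of the other genome, in those libraries only. Margins were small outside replicate 1, as in C. albicans alone replicate 3 (mean correlation 0.624 with its own side, 0.622 with the other), against 0.924 and 0.900 in replicate 1. The C. albicans totals above also hold ribosomal RNA and other features, which these correlations did not cover. In 4 of 4 replicate 1 libraries, the 3 best of 9 such correlations were with replicate 1 libraries. Mixing or index misassignment between libraries handled together would give this and may account for the counts of these 4 libraries. The test rests on the same correlations as the one above. For the C. albicans counts in S. gordonii in C. albicans medium, material left in that medium stays open: the share was 4.45, 1.02 and 1.59 times that in S. gordonii alone in replicates 1, 2 and 3. No biological explanation was tested.

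C. albicans genes higher in co-culture than alone were weighed next. Bacterial reads counted on fungal genes, at the highest rate that the counts of any S. gordonii library allow (95% Poisson limit), would make up at most 1.62% of the co-culture counts of the 19 genes that rose without the block, which argues against that source. For the 99 that rose with the block the median was 0.485%, and 1 gene, orf19.6501 with 71 co-culture counts, reached 10.1%, above the 10% set for excluding the source, which stays open there. For the arginine list, the upper quartile was 0.325 in medium against alone, and the quartiles in co-culture against alone were 2.75 and 3.36. In co-culture against medium they were 2.22 and 3.13. This goes against the further hour as the source of rises of that size. Quartiles run over genes and do not measure the spread between libraries. Against medium no list passed camera with an estimated correlation (lowest adjusted p = 0.227), so that the further hour is not excluded. Lower depth of the co-culture libraries is argued against by thinning, after which 22 of the 26 calls remained. The presence of S. gordonii cells may account for the rises of the arginine list as a hypothesis found and weighed on the same data. Other effects of adding cells, such as a change of the medium, were not tested. For the other genes that rose the further hour was not weighed. Of the 19 genes, 3 also rose against medium without the block. In medium against alone CPH1 and ALS3 had log2 fold changes of 1.07 and 1.24, against 1.33 and 2.08 in co-culture against alone.

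For hypha-associated genes, higher in co-culture than alone, the further hour before harvest stays open: medium against alone gave an adjusted p of 0.00468 with an estimated correlation but 0.0822 with the block, and co-culture against alone 0.00908 and 0.124. An addition by S. gordonii cells beyond that hour stays open, since co-culture against medium gave an adjusted p of 0.227 with an estimated correlation (0.376 with the block). The medium group held both the hour and the medium, which cannot be told apart. The labels give 2 h for C. albicans alone and no later step, and the further hour, here and for the arginine list, rests on reading this as the time of harvest.

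Other splits of the 6 libraries of a comparison were also counted. The 10 splits, or the 4 that part every replicate pair in fits with the block, include the real one and are too few for a share under 0.05. For co-culture against C. albicans alone, no other of the 10 splits gave as many genes as the real one (26, highest other 0). Nor did any other of the 4 with the block (154, highest other 0). For medium against alone the real split gave 0 genes, which every split reaches by definition (highest other 0). With the block no other of the 4 gave as many as the real one (2, highest other 0), and splits that part 1 pair gave at most 1. For co-culture against medium no other of the 10 gave as many as the real one (3, highest other 0), and no other of the 4 with the block (79, highest other 0). For S. gordonii the real split gave 0 genes in each comparison, which every split reaches by definition. The highest others were 55 for co-culture against alone, 2 for medium against alone and 0 for co-culture against medium. In the last, the real split and the highest other also gave 0 with the block. The split with 55 set co-culture replicate 1 and replicates 1 and 3 of S. gordonii alone against the others, which points to a structure of the samples.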

How the results depend on the processing

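The fits without replicate 1 libraries and DESeq2 with the block were chosen after seeing the data; the other alternatives were planned. The cause of the differences was not tested.

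For C. albicans in co-culture against alone (26 genes), DESeq2 gave 137, the 2 compared groups alone 2, the replicate block 154, DESeq2 with the block 375, no replicate 1 libraries 222, the same with the block 320, and leaving out 1 library 2 to 58. Library totals gave 22, median-ratio factors 23, thinning to the smallest total 23, 22 of them among the 26, and no filter, the stricter filter and noncoding features each 26. For medium against alone (0) the counts were DESeq2 4, block 2, DESeq2 with block 39, no replicate 1 libraries 4, with block 18, and 0 without any 1 library. For co-culture against medium (3) they were DESeq2 63, the 2 groups alone 5, block 79, DESeq2 with block 201, no replicate 1 libraries 107, with block 193, and 2 to 37 without 1 library.

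For S. gordonii in co-culture against alone (0), DESeq2 gave 56, the block 24, DESeq2 with block 133, no replicate 1 libraries 46, with block 193, and leaving out 1 library 0 to 138. Beside the 24, another split gave 22 genes with the block. It set co-culture replicate 1 and replicates 1 and 3 of S. gordonii alone against the others. The replicate numbers did not pair these libraries (lowest correlation 0.0201), nor those of medium against alone (0.0474). For medium against alone (0), DESeq2 with block gave 15, and DESeq2 and edgeR with the block gave 0 each. For co-culture against medium (0), DESeq2 gave 11, DESeq2 with block 82, no replicate 1 libraries 20, with block 243, and leaving out 1 library 0 to 32. Fits without co-culture replicate 1 hold only the co-culture libraries labelled CH2 and CH3, where a difference of substrain cannot be told apart from co-culture.

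Lists past camera numbered 10, 11 and 9 for C. albicans (co-culture against alone, medium against alone, co-culture against medium). With an estimated correlation there were 1, 1 and 0, with fry in one direction 2, 1 and 0, and with fry in mixed directions 6, 1 and 5; fry tests a list against no change, not against other genes. For S. gordonii they numbered 4, 7 and 2, with 0, 0 and 0 for an estimated correlation, 0, 0 and 0 for fry in one direction, and 1, 0 and 0 for mixed directions.

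Over 194 values of named genes, of which 21 passed, the alternatives ended a call 102 times, added one 436 times and reversed a direction 13 times. Reversed log2 fold changes follow, with the range when 1 library was left out. In co-culture against alone, NAD3 was 0.00399 (-1.44 to 0.00399) and NAD2 0.0485 (-0.96 to 0.0485) without C. albicans alone replicate 1. In medium against alone, ARG5,6 was -0.00595 without medium replicate 1 (-0.00595 to 0.52), -0.252 without replicate 1 libraries and -0.241 with the block added, and CPA1 was -0.00888 without C. albicans alone replicate 1 (-0.00888 to 0.68). In co-culture against medium, RPL29 was 0.284 and 0.297 without co-culture replicates 2 and 3 and 1.07 without medium replicate 1 (-2.34 to 1.07), and without the last HSP12 was 0.0263 (-4.11 to 0.0263) and WH11 0.177 (-4.31 to 0.177). In S. gordonii in medium against alone, SGO_1789 was 0.166 without S. gordonii alone replicate 2 (-2.28 to 0.166) and pyrE -0.0241 without medium replicate 2 (-0.0241 to 1.46).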

Other observations

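The genes in this part were chosen after their values were seen. In C. albicans in co-culture against alone with the replicate block, the flavohemoglobin-related genes YHB4 and YHB1 rose by 1.59 on the log2 scale (SE 0.22, adjusted p = 0.00252 by edgeR) and 1.22 (SE 0.27, adjusted p = 0.0377). Genes that fell included CSP37 (-2.08, SE 0.23, adjusted p = 0.000682), PIR1 (-1.38, SE 0.22, adjusted p = 0.00461) and CHT2 (-1.61, SE 0.22, adjusted p = 0.00217), and the retrotransposon reading frames orf19.2669 (-1.21, SE 0.20, adjusted p = 0.00664) and orf19.2668.1 (-1.11, SE 0.18, adjusted p = 0.00610), while orf19.7278 and orf19.2372 of another retrotransposon rose by 0.95 (SE 0.19, adjusted p = 0.0218) and 0.95 (SE 0.21, adjusted p = 0.0371).

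For S. gordonii in co-culture against alone, DESeq2 called 56 genes, 8 of which follow. SGO_1134, SGO_1135 and SGO_1136 had log2 fold changes of 1.87, 1.71 and 1.59, and the cellobiose phosphotransferase genes celC and celD of 0.93 and 1.01. The sugar and polysaccharide enzyme genes SGO_2021, SGO_2022 and SGO_2023 stood at 1.02, 1.15 and 1.34. The glycerol kinase gene glpK, not among the calls, varied between libraries, at 602, 913 and 1241 CPM in co-culture replicates 1, 2 and 3 and 39.3, 56.6 and 271 alone.

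Comparisons that share a group are correlated by design. For C. albicans, log2 fold changes of co-culture against alone and medium against alone correlated across genes, which are not independent replicates, at 0.497, where 20 simulated draws without effects gave 0.482; covariances were 0.0871 and 0.0460. With the block the correlation was 0.469, below the simulated 0.480, and the covariances were 0.0788 and 0.0437. For S. gordonii the values were 0.639 and 0.508, with covariances of 0.142 and 0.0556.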
